A study of Mus musculus with 18 samples.

How the data were processed

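Polyadenylated RNA was sequenced from macrophages grown from the tibial bone marrow of mice 2 to 3 months old, per the labels' protocols. The mice carried loxP-flanked Smad1 alleles, either alone (labelled floxed here) or with Cre recombinase expressed from the lysozyme M gene Lyz2 (labelled knockout here). Marrow cells were kept for 24 h in medium with 15% serum, WEHI-3 conditioned medium and 12 ng/ml CSF-1, and the non-adherent cells were reseeded in 120 ng/ml CSF-1 for 48 h. After about 16 h without serum, cells were left untreated or given 10 ng/ml TGF-β1 or 50 ng/ml BMP4 for 4 h. The 6 groups hold 3 libraries each, numbered 1 to 3 in the labels. Because the labels do not say that the libraries of a group came from separate animals or cultures, p-values here measure the spread between these libraries, part of which may be technical. It is not all technical in the floxed-labelled groups, where the libraries numbered 1 differ from the others in Lyz2 in each treatment.

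Per the submitters' processing notes, paired reads of 150 bp were aligned to the mouse genome build mm10 (GRCm38.p6) with TopHat2 2.0.9, counted per gene with HTSeq 0.6.1 and scaled with Cufflinks 2.1.1. The count columns of the deposited table are read counts per gene, per the file headers, and were used with no change. The FPKM columns are the authors' scaled values, and within a library each deposited FPKM equalled the count divided by the gene length times a constant to within 1e-06 of its value in 100% of the genes checked. The log2 fold change and p-value columns of the deposited table hold the authors' own comparisons, per the file headers, and were used only for a side-by-side count of calls. The table holds 54532 genes and 78 further columns of per-sample values, of which 36 repeat the counts or FPKM and 42 are scaled per comparison, and these were not used. The notes do not state whether counting used strand, so genes that overlap an antisense partner, and Lyz2 with its neighbouring copy Lyz1, are uncertain. Coordinates are those of the deposited table (mm10), and 53499 of 54409 gene identifiers had identical coordinates in GENCODE release 21 of that build. Symbols were shared by more than 1 gene in 203 cases.

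Total counts ran from 15153296 to 24639163 per library, so a floor of 3 counts lay between 0.122 and 0.198 CPM (counts scaled to a common library total, with TMM factors except in these floors). Floors cover counting error only. All pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 3.694 to 28.646), so none was a repeat deposit of another.

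Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling (factors 0.978 to 1.02), filterByExpr over the 6 groups, which left 14684 genes, and a quasi-likelihood F test with 1 mean per group over all 18 libraries (12 residual and 6.41 prior degrees of freedom, biological coefficient of variation 8.86%). "edgeR adjusted p" stands for that test's two-sided p with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an edgeR adjusted p under 0.05. Values per group are CPM as mean ± SD of 3 libraries, and fold changes are log2 with their SE. The 25 gene lists named in the report were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), two-sided. "Camera adjusted p" stands for its p with Benjamini-Hochberg adjustment over the lists within a comparison. Counts per list are given over all genes tested and, where they differ, adjusted over the list alone by edgeR.

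Genes are named by a fixed rule. It takes, in each comparison, the 6 largest rises and the 6 largest falls among called genes whose 3 libraries did not overlap between groups, with a mean of at least 1 CPM in the higher group and no predicted-gene name. It also takes up to 4 called members per list in each direction by lowest adjusted p, or the 2 most abundant members where none was called, and in every comparison Smad1, Smad5, Smad9, Id1, Id2, Id3, Smad6, Smad7 and Lyz2. Not every gene that this rule takes is reported here. By chance, 3 libraries against 3 do not overlap for 10% of genes. Groups, comparisons, tests, lists and this rule were chosen before the data were examined. Genes outside the rule are named as chosen after their values were seen.

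The alternatives chosen in advance were size factors by median of ratios (RLE), total count scaling, no low-count filter (29506 genes), a mean of at least 1 CPM (12234 genes), a DESeq2 1.42.0 Wald test, a fit of only the groups compared, a block for library number over all groups or within genotype, limma on log2(FPKM + 1) or log2(FPKM + 0.1), and each library left out in turn. Alternatives added after seeing the data were a fit of 15 libraries without the floxed-labelled libraries numbered 1, in which Lyz2 was near 0 (15031 genes), and the share of counts in genes of biotype TEC, the annotation's class for transcripts awaiting experimental support, as a covariate.

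The numbers pair libraries within a genotype label. Deviations from the group means correlated at 0.11 to 0.33 in all 18 pairs of libraries with the same genotype label and number, against −0.26 to 0.06 in 36 pairs with another number and −0.11 to 0.07 in 27 same-numbered pairs across genotype labels. In the 54 pairs that differ in both label and number the range was −0.16 to 0.13, with 3 above 0.1. The pairing comes from this check alone, since the labels give no animal or day. The main fit treats paired libraries as independent when it estimates the spread, and the genotype comparisons were not fitted with this pairing. Their p-values may therefore be too small. With a replicate block within genotype the 84 genes called for BMP4 in knockout-labelled cells became 472, and blocked values stand beside calls of genes and lists that they change. Blocked counts of list members are given only for TGF-β1 in floxed-labelled cells, for the lists whose balance they change and 2 others.

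The fit was tested on simulated counts for the 14684 genes, with 50 genes changed at each fold. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery below that level was not measured. For untreated knockout against floxed libraries it recovered 38% at 1.25-fold, 72% at 1.5-fold, 82% at 2-fold and 96% at 4-fold, with 7 false calls among 151. For BMP4 against untreated floxed libraries it recovered 40%, 64%, 90% and 98% at those folds. For the interaction of BMP4 and genotype it recovered 6%, 58%, 76% and 98%. The camera test of a list raised 1.3-fold gave an adjusted p of 8.84e-22 and called 0 of the other lists. Genes were simulated independently, so this does not test the preset correlation on lists whose members vary together. Libraries were simulated without the pairing found above, so the false calls do not measure its effect.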

Results

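Gene expression was measured by RNA sequencing in cultured mouse bone marrow macrophages that were labelled either floxed (loxP-flanked Smad1, no Cre) or knockout (the same alleles with Cre driven from Lyz2). Cells of each label were left untreated, given TGF-β1 or given BMP4 for 4 h, which makes 6 groups of 3 libraries numbered 1 to 3. Smad1 is a signal transducer that BMP receptors phosphorylate, and the comparisons ask what each ligand changes and how the answer differs between the genotype labels. Total counts were 16166856, 16533837 and 15989866 in the untreated knockout-labelled libraries, 15153296, 18636282 and 19064269 with TGF-β1, and 21394840, 19333829 and 19951359 with BMP4. In floxed-labelled libraries they were 23086927, 21233858 and 18565040 untreated, 18092617, 24639163 and 24095015 with TGF-β1, and 21540821, 17947329 and 22174918 with BMP4. The 10 most abundant genes held 7.3% to 8.6% of the counts and mitochondrial genes 1.02% to 1.26%. The first principal component of log2 CPM held 46.6% of the variance, and the next components held 7.9% and 6.3%.

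Smad1 (ENSMUSG00000031681, chromosome 8, 79338395 to 79399518, build mm10), the targeted gene, was present in every library. Untreated knockout-labelled libraries 1 to 3 held 26.8, 26 and 26 CPM, against 30, 30.8 and 31.1 CPM in the floxed-labelled ones. With TGF-β1 the values were 20.4, 23.6 and 19.5 CPM against 26.3, 24.6 and 22.2 CPM, and with BMP4 26.2, 24.8 and 24.3 CPM against 31, 29.7 and 27.6 CPM. Knockout-labelled means were thus 0.858 of the floxed-labelled level untreated (log2 −0.22, SE 0.08, edgeR adjusted p = 0.13), 0.869 with TGF-β1 (log2 −0.20, edgeR adjusted p = 0.278) and 0.853 with BMP4 (log2 −0.23, edgeR adjusted p = 0.44). None of the 3 differences passed the test over all genes. For this 1 gene, chosen in advance, the edgeR p without adjustment was 0.0097 untreated, 0.0184 with TGF-β1 and 0.00737 with BMP4. The labels do not say which exon is flanked by loxP sites, and a count over the whole gene may hold reads from exons outside the deleted part, so Smad1 neither checks nor refutes the genotype labels.

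Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), which encodes lysozyme and hosts the Cre insertion in LyzM-Cre mice, went against the genotype labels. It was highest in the 9 knockout-labelled libraries (median 15700 CPM, range 13400 to 17800). The floxed-labelled libraries numbered 2 and 3 held a median of 9620 CPM (range 8120 to 9870), and the 3 numbered 1 held 62.1 CPM untreated, 37.6 CPM with TGF-β1 and 74.3 CPM with BMP4. Mean Lyz2 was 6500 ± 5580 CPM in floxed-labelled and 16000 ± 1140 CPM in knockout-labelled untreated cells (2.47-fold, SE 1.34 in log2, edgeR adjusted p = 0.677). Groups are therefore called by their labels below, and every direction between genotypes rests on labels that Lyz2 contradicts. Lyz1 (ENSMUSG00000069515), the adjacent near-copy of Lyz2, was 10.7 ± 1.96 CPM in floxed-labelled and 5.3 ± 0.202 CPM in knockout-labelled untreated cells, and reads shared by the copies cannot be told apart.

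**Figure D1:**
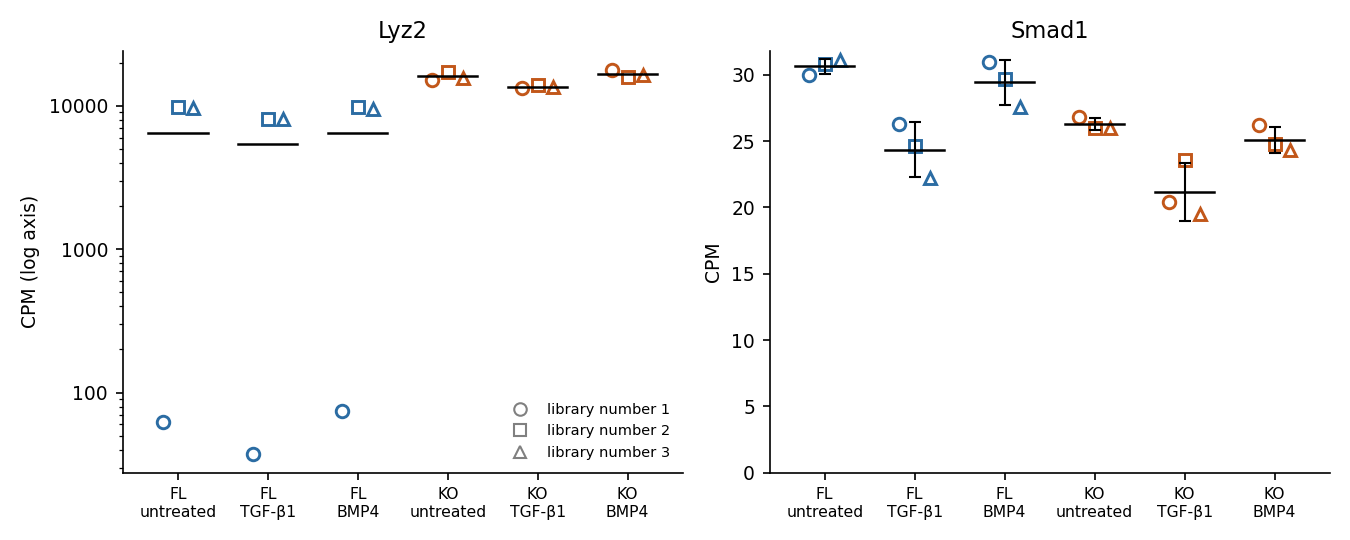
Lyz2 (CPM, log axis) and Smad1 (CPM, linear axis) in each of the 18 libraries by group, with group mean and SD on the Smad1 panel; circles, squares and triangles mark library numbers 1, 2 and 3, blue floxed-labelled and orange knockout-labelled. The floxed-labelled libraries numbered 1 lie between 37.6 and 74.3 CPM for Lyz2, while the 9 knockout-labelled libraries lie between 13400 and 17800 CPM.

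TGF-β1 against no treatment in floxed-labelled cells asks which genes the ligand changes where Smad1 is intact per the labels. Pmepa1 (ENSMUSG00000038400, chromosome 2, 173224458 to 173276533), a membrane protein that restrains TGF-β signalling, rose 227-fold, from 0.903 ± 0.264 to 203 ± 9.92 CPM (log2 7.83, SE 0.11, edgeR adjusted p = 1.18e-19). Smad7, an inhibitory Smad, rose from 4.52 ± 0.615 to 47 ± 5.81 CPM (log2 3.38, SE 0.12), and Spsb1, which promotes loss of a TGF-β receptor, from 1.99 ± 0.248 to 86.1 ± 2 CPM (log2 5.42). The inhibitors of DNA binding Id2 and Id3, usual targets of BMP signalling, rose by log2 1.67 (SE 0.07) and 4.17 (SE 0.50), and Smad6 by log2 4.61 (SE 0.33). The largest falls included Gprc5c, an orphan receptor (log2 −4.30, SE 0.24), and Slc40a1, the iron exporter ferroportin (log2 −3.63, SE 0.23, from 381 ± 50.2 to 30.7 ± 8.27 CPM). In all, 4841 genes were called, 2491 higher and 2350 lower, of which 632 rose and 570 fell at least 2-fold.

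Of 27 measured TGF-β and Smad3 target genes, 20 rose and 3 fell (20 and 4 adjusted over the list alone, camera adjusted p = 8.4e-13), among them Ski, a Smad repressor (138 to 405 CPM). It was the 1 list of this comparison still called with an estimated correlation (adjusted p = 0.0236). The cell cycle inhibitor Cdkn2b and Tgfb1 itself fell (log2 −1.51 and −0.24). Of 14 BMP and Smad1/5 targets 10 rose and 3 fell (camera adjusted p = 0.00108, adjusted p = 0.0805 with an estimated correlation), including Runx2 (7.2 to 25.3 CPM) and Id1, which lay near the floor. Smads, ligands and receptors of the family moved both ways (8 rose and 8 fell of 25, camera adjusted p = 0.999): the receptors Tgfbr1 (265 to 968 CPM) and Acvr1 rose (log2 1.87 and 0.92), while Nrros, which holds latent TGF-β at the cell surface (308 to 110 CPM), Bmp2 and Smad1 fell (log2 −1.48, −3.30 and −0.33).

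Genes of angiogenic growth factors also rose, 10 of 18 against 2 that fell (camera adjusted p = 0.0193, adjusted p = 0.101 with an estimated correlation). Pdgfa rose from 7.38 ± 1.15 to 129 ± 19.4 CPM (log2 4.12, SE 0.13), Pdgfb from 48.1 to 266 CPM (log2 2.47, SE 0.07) and Hgf from 36.3 to 85.5 CPM, while Nrp1 and Igf1 fell (log2 −1.01 and −0.59). Of 8 angiogenic chemokines, Cxcl16 rose (296 to 651 CPM) and 3 fell, or 5 adjusted over the list alone (camera adjusted p = 0.536), with Cxcl2 at 14.8 and 4.3 CPM. Of 4 angiostatic chemokines Cxcl14 rose (12.2 to 60.1 CPM, camera adjusted p = 0.547). Among 14 other CC chemokines and chemokine receptors 3 rose and 6 fell (camera adjusted p = 0.249): the fractalkine receptor Cx3cr1 rose from 173 ± 36.3 to 1010 ± 48.5 CPM and Cxcr4 from 89 to 458 CPM, while Ccl3, Ccl4 and Ccl9 fell (log2 −1.71, −1.89 and −1.17). Of 28 matrix genes 5 rose and 2 fell (camera adjusted p = 0.567), with Tgfbi, an adhesive matrix protein, at 179 and 1240 CPM. Of 26 matrix proteases and their inhibitors 11 rose and 2 fell, or 3 adjusted over the list alone (camera adjusted p = 0.0198, adjusted p = 0.2 with an estimated correlation, 0.0546 without floxed-labelled untreated library 2), including the urokinase gene Plau (27.5 to 257 CPM) and its receptor Plaur (log2 1.37).

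Interferon-stimulated genes fell in 21 of 30 cases and 1 rose (1 and 23 adjusted over the list alone, median log2 −0.58, camera adjusted p = 2.75e-05, adjusted p = 0.926 with an estimated correlation). Cmpk2 fell from 66.2 to 21.7 CPM and Ddx58, the RNA sensor RIG-I, from 220 to 123 CPM. Of 22 pro-inflammatory genes 10 fell and 4 rose (camera adjusted p = 0.0391, adjusted p = 0.926 with an estimated correlation). That call was lost without floxed-labelled untreated library 2 (0.152) or TGF-β1 library 1 (0.135), in the 15 libraries (0.0795) and with the replicate block within genotype (0.0618). Tlr4 fell (107 to 48.3 CPM) and Tlr2 rose (269 to 608 CPM). Hypoxia and glycolysis genes rose in 18 of 26 cases and 2 fell (median log2 0.41, camera adjusted p = 2.75e-05, adjusted p = 0.0805 with an estimated correlation), with hexokinase Hk2 at 57.9 and 226 CPM, while Ndrg1 fell (70.6 to 19.3 CPM). Of 19 alternative activation genes 6 rose and 7 fell, or 7 and 8 adjusted over the list alone. Their median was log2 0.17 but their mean −0.34, and the test pointed down (camera adjusted p = 0.567). Tgm2 rose (29.7 to 144 CPM) and the scavenger receptor Cd163 and mannose receptor Mrc1 fell (17.6 to 1.75 and 1200 to 621 CPM).

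Phagocytosis receptors moved both ways (7 rose and 9 fell of 25, median log2 −0.01, mean 0.16, camera adjusted p = 0.77), with integrin Itgb5 higher (244 to 1100 CPM) and the β-glucan receptor Clec7a lower (204 to 76.6 CPM). Of 32 cell cycle genes 7 rose and 1 fell, or 5 and 0 adjusted over the list alone, with Mcm6 at 73.8 and 197 CPM (camera adjusted p = 0.172). That list was called without untreated library 1 (0.0499) or 3 (0.0257) or without TGF-β1 library 2 (0.0196). Of 31 cholesterol and lipid genes 4 rose and 4 fell (median −0.01, mean 0.02, camera adjusted p = 0.999), with Abca1 higher (423 to 954 CPM) and Lpl lower (3760 to 1580 CPM). Of 23 immediate early and heat shock genes 6 rose and 5 fell (camera adjusted p = 0.553), with Junb at log2 1.39 and Klf2 at −0.99. Cell type markers gave no call: macrophage markers (3 rose and 2 fell of 18, median and mean log2 −0.01 with the test pointing up, camera adjusted p = 0.999), of which Cd14 fell from 481 to 224 CPM, neutrophil (1 rose of 14, 0.553), monocyte (1 rose of 11, 0.999), dendritic (2 and 2 of 15, 0.999), fibroblast (0 of 8, median 0.11 with the test pointing down, 0.905), osteoclast (1 and 1 of 8, 0.905), lymphoid, mast, erythroid and platelet (0 of 5, 0.999) and sex-linked genes (1 of 4, 0.999). With the replicate block within genotype more members were called, and the balance moved down for macrophage markers (5 rose and 7 fell), monocyte markers (1 and 4), cholesterol and lipid genes (6 and 10), Smads and receptors (8 and 10) and osteoclast markers (2 and 3). It moved up for dendritic markers (3 and 2) and stayed up for neutrophil markers (5 and 1) and cell cycle genes (12 and 2).

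**Figure D2:**
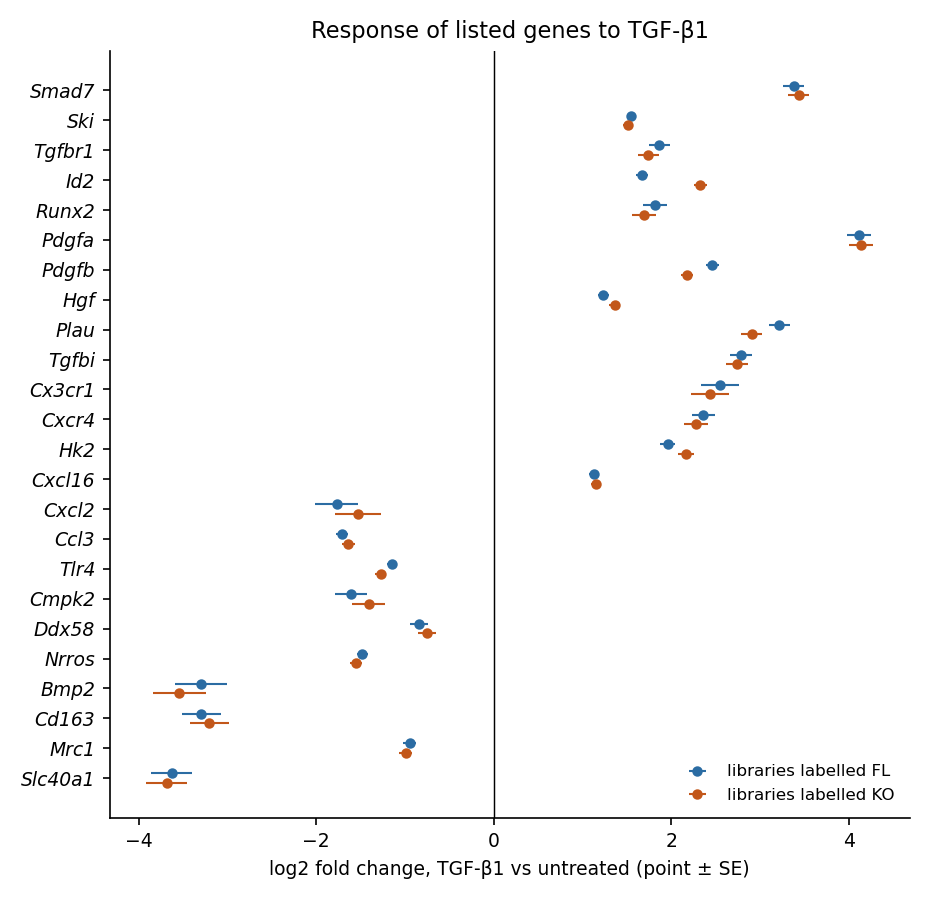
Log2 fold change of 24 genes from the lists after TGF-β1 against no treatment (x axis), in floxed-labelled (blue) and knockout-labelled (orange) cells; points are fitted values and bars their SE. Pdgfa lies at 4.12 and 4.14, Id2 at 1.67 and 2.33, and Slc40a1 at −3.63 and −3.69.

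TGF-β1 against no treatment in knockout-labelled cells asks for the same response where Smad1 is deleted per the labels, which Lyz2 contradicts. Pmepa1 rose from 0.878 ± 0.24 to 194 ± 10 CPM (log2 7.77, SE 0.12, edgeR adjusted p = 2.88e-19). Id3 (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755) rose 40.4-fold, from 1.22 ± 0.362 to 49.8 ± 2.96 CPM (log2 5.33, SE 0.50, edgeR adjusted p = 5.41e-08). Id2 (ENSMUSG00000020644, chromosome 12, 25093799 to 25097140) rose from 17.4 ± 1.34 to 87.5 ± 3.61 CPM (log2 2.33, SE 0.07, edgeR adjusted p = 9.98e-15), and Smad6 (ENSMUSG00000036867) from 1.21 ± 0.454 to 37 ± 2.36 CPM (log2 4.93, SE 0.33). The largest falls included Gprc5c (log2 −4.37, SE 0.24) and the aryl hydrocarbon receptor Ahr (log2 −4.09, SE 0.20, from 6.96 ± 0.365 to 0.407 ± 0.0524 CPM). Smad1 fell as well (log2 −0.31, edgeR adjusted p = 0.00425). In all, 5084 genes were called, 2578 higher and 2506 lower, with 595 rising and 626 falling at least 2-fold.

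Of 27 TGF-β targets 19 rose and 3 fell (camera adjusted p = 2.42e-11, adjusted p = 0.0372 with an estimated correlation). BMP targets rose in 10 of 14 cases and 2 fell (camera adjusted p = 0.000449, adjusted p = 0.087 with an estimated correlation). Of 18 angiogenic growth factors 9 rose and 2 fell (camera adjusted p = 0.0184, adjusted p = 0.0981 with an estimated correlation), with Pdgfa at 6.78 and 120 CPM and Pdgfb at 64.1 and 291 CPM. Interferon-stimulated genes fell in 17 of 30 cases and 1 rose (1 and 19 adjusted over the list alone, camera adjusted p = 0.000449, adjusted p = 0.884 with an estimated correlation). Hypoxia and glycolysis genes rose in 18 of 26 cases and 2 fell (camera adjusted p = 0.000286, adjusted p = 0.0981 with an estimated correlation). Of 26 proteases and inhibitors 11 rose and 3 fell (camera adjusted p = 0.0281, adjusted p = 0.236 with an estimated correlation). The cell cycle list (8 rose and 2 fell of 32, or 7 and 2 adjusted over the list alone, camera adjusted p = 0.134) was called without TGF-β1 library 2 (0.0369) and with the replicate block within genotype (0.0417). The pro-inflammatory list (4 rose and 9 fell of 22, camera adjusted p = 0.101) was called without untreated library 2 (0.0292), TGF-β1 library 1 (0.0434) or 3 (0.037).

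The responses of the 2 genotype labels, which share no library, ran together. Across genes, which are not independent replicates, log2 changes correlated at a Pearson r of 0.84 (Spearman 0.75), and at 0.98 for the 8601 genes with a mean of at least 10 CPM. Of the 4841 genes called in floxed-labelled cells 4792 (99%) had the same sign in knockout-labelled cells. Calls in both numbered 2031 higher (437.3 expected of independent lists), 1940 lower (401.1 expected) and 0 in opposite directions.

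**Figure D3:**
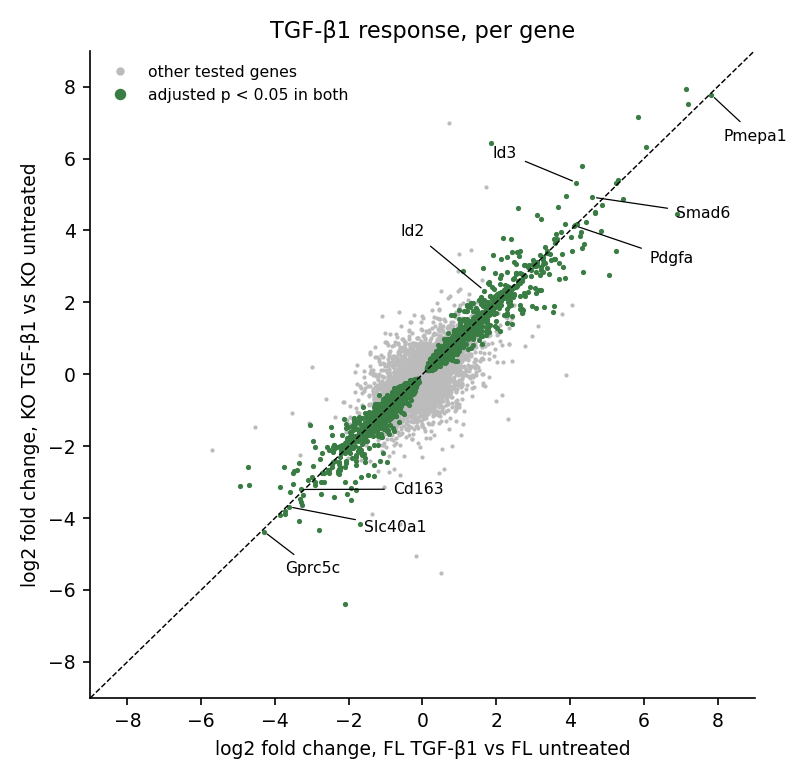
Log2 fold change after TGF-β1 in floxed-labelled (x axis) against knockout-labelled cells (y axis), one point per gene tested; green points passed an edgeR adjusted p of 0.05 in both. Points lie near the diagonal (Pearson r 0.84 over all 14684 genes), and Id2 lies above it at 1.67 and 2.33.

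Id2 was the 1 gene called for a different response to TGF-β1 between the genotype labels: its rise was larger in knockout-labelled cells by log2 0.65 (SE 0.10, edgeR adjusted p = 0.0433). Id2 lay at 22.2, 19.7 and 20.9 CPM in untreated floxed-labelled libraries and at 61.8, 70.6 and 68.3 CPM with TGF-β1, against 18.6, 17.6 and 16 CPM and then 91.3, 87.1 and 84.2 CPM in knockout-labelled ones. The differences for Id3 (log2 1.17, edgeR adjusted p = 1) and Smad6 (log2 0.32, edgeR adjusted p = 1) did not pass. By edgeR 493 genes had an unadjusted p under 0.05. The Id2 call was kept without knockout-labelled untreated library 1 or floxed-labelled untreated library 2 and lost without any other of the 12 libraries (edgeR adjusted p 0.0518 to 0.301), with the replicate block over all groups (0.105), with the TEC share as a covariate (0.101) and in the 15 libraries (log2 0.56, 1). It was kept with the block within genotype, which follows the pairing found (log2 0.66, edgeR adjusted p = 0.0128). Of the lists, cholesterol synthesis was called lower in the knockout minus floxed difference with the replicate block within genotype (camera adjusted p = 0.0016, against 0.308 without it). The blocked list test was run with the preset correlation only.

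BMP4 against no treatment in floxed-labelled cells asks which genes BMP4 changes where Smad1 is intact per the labels. Id3 was 1.11 ± 0.327 CPM untreated and 7.19 ± 4.67 CPM with BMP4 (log2 2.68, SE 0.54, edgeR adjusted p = 0.239), with 1.88, 10.6 and 9.05 CPM in the BMP4 libraries. Id2 was 20.9 and 22.1 CPM (log2 0.07, SE 0.07, edgeR adjusted p = 0.853) and Smad6 log2 0.61 (edgeR adjusted p = 0.798). edgeR called 0 genes, with 1103 at an unadjusted p under 0.05, DESeq2 called 14, and with the replicate block within genotype edgeR called 53, 16 higher and 37 lower. In that blocked fit Id3 rose (log2 2.61, SE 0.26, edgeR adjusted p = 4.65e-06), as did Dmpk, a muscle kinase gene (0.642 to 2.09 CPM, log2 1.70, edgeR adjusted p = 0.0269), and the fatty acid binding protein Fabp5 (log2 0.28, edgeR adjusted p = 0.0146). Ly6c2, a surface marker of inflammatory monocytes (11.7 to 7.19 CPM, log2 −0.70, edgeR adjusted p = 0.0146), the folate receptor Folr2 (log2 −0.43, edgeR adjusted p = 0.0149) and the adhesion protein Tns1 (91.8 to 71.2 CPM, log2 −0.36, edgeR adjusted p = 0.00574) fell. Apart from Id3 these genes lie outside the rule for this comparison and were named after their values were seen. Without BMP4 library 1 the unblocked test called 1 gene, Id3 (log2 3.14, edgeR adjusted p = 0.00395), and without untreated library 2 it called 1, Soga1, named after its value was seen.

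Cell cycle genes were lower with BMP4 in floxed-labelled cells as a list (median log2 −0.17, camera adjusted p = 0.000948, adjusted p = 0.961 with an estimated correlation). That call was lost without untreated library 1 (0.127) or 3 (0.216), without BMP4 library 2 (0.0536) and in the 15 libraries (0.107). Hypoxia and glycolysis genes were lower too (median log2 −0.07, camera adjusted p = 0.00249, adjusted p = 0.404 with an estimated correlation, 0.0612 without untreated library 3, 0.0513 without BMP4 library 1 and 0.0723 in the 15 libraries). Sex-linked genes were higher (camera adjusted p = 0.00225, adjusted p = 0.063 with an estimated correlation), 3 of 4 adjusted over the list alone. No member of these lists was called over all genes. Monocyte markers were called with the replicate block within genotype (camera adjusted p = 0.00453, against 0.118 without it) and without BMP4 library 3 (0.0237).

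BMP4 against no treatment in knockout-labelled cells asks for the same response where Smad1 is deleted per the labels, which Lyz2 contradicts. Id3 rose 12.6-fold, from 1.22 ± 0.362 to 15.5 ± 4.44 CPM (log2 3.66, SE 0.52, edgeR adjusted p = 0.00509). Id2 rose from 17.4 ± 1.34 to 26.5 ± 1.56 CPM (log2 0.60, SE 0.07, edgeR adjusted p = 0.00122), and Dmpk from 0.673 ± 0.432 to 5.26 ± 3.02 CPM (log2 2.95, SE 0.57, edgeR adjusted p = 0.0252). Tns1 fell from 89.2 ± 4.11 to 59.3 ± 4.1 CPM (log2 −0.59, SE 0.08, edgeR adjusted p = 0.00232), Muc6, a mucin gene, from 6.93 ± 1.39 to 2.39 ± 0.42 CPM (log2 −1.53, edgeR adjusted p = 0.0115) and the scavenger and efferocytosis receptor Lrp1 from 4210 ± 160 to 3450 ± 318 CPM (log2 −0.29, edgeR adjusted p = 0.0477). edgeR called 84 genes, 19 higher and 65 lower. With the replicate block within genotype it called 472, 167 higher and 305 lower, which included all 84, and Smad6 passed (log2 1.12, SE 0.28, edgeR adjusted p = 0.0232, against 0.246 without the block). Of 14 BMP targets 2 rose (camera adjusted p = 0.135, or 0.0187 without BMP4 library 1), and no list was called.

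Leaving out 1 library changed the count for BMP4 in knockout-labelled cells to 4 without untreated library 1 (Zbtb20, Tns1, Id2 and Id3, the first chosen after its values were seen), to 112 without untreated library 2 and to 14 without untreated library 3. It was 11, 12 and 22 without BMP4 libraries 1, 2 and 3. Id3, Id2 and Tns1 were called in each of these fits, while Lrp1 was called in none (edgeR adjusted p 0.0513 to 0.213). Dmpk was called only without BMP4 library 2 (edgeR adjusted p 0.0599 to 0.115 without any other), and Muc6 was lost without untreated library 1 (0.0902) or BMP4 library 2 (0.0513). A fit of only the groups compared called Tns1 and Id3 alone, and with the TEC share as a covariate no gene was called. Of the 65 genes that fell, 31 were protein-coding and 18 were TEC transcripts, a class that was also higher in untreated knockout-labelled libraries.

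**Figure D4:**
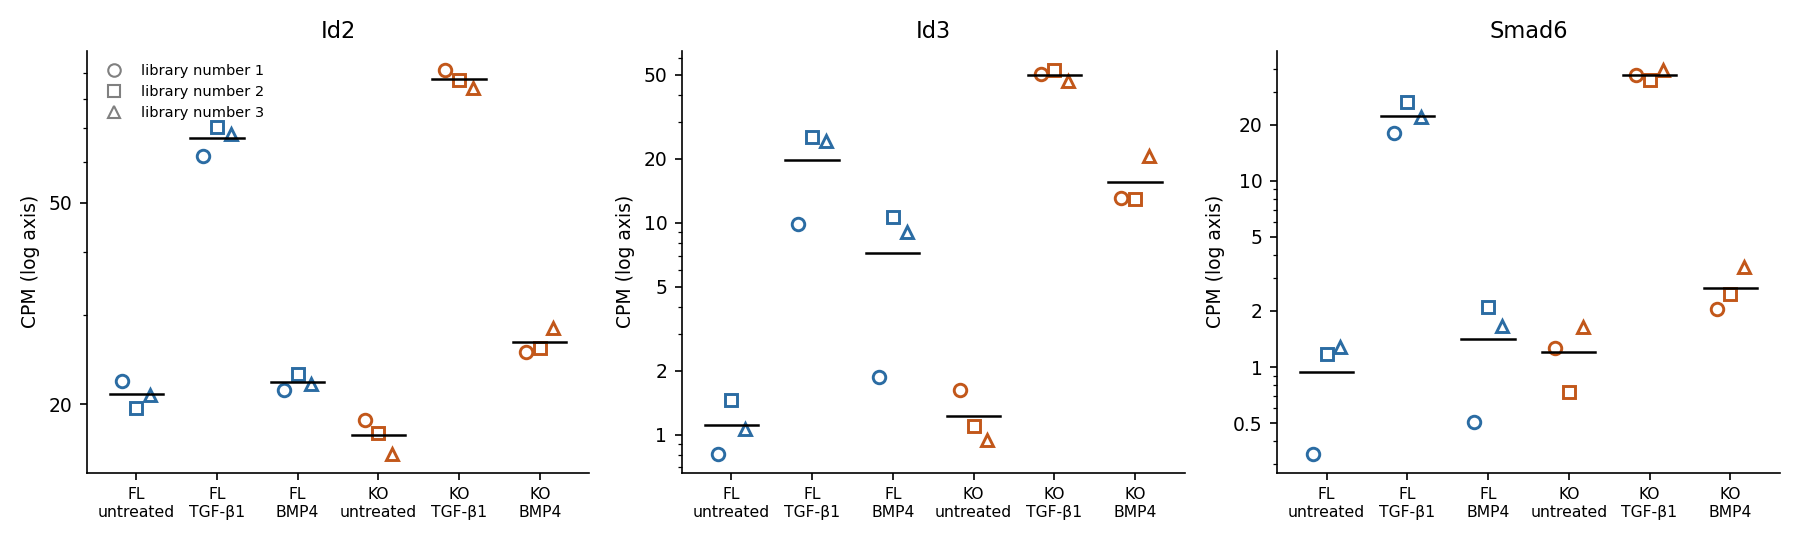
Id2, Id3 and Smad6 (CPM, log axis) in each library by group; circles, squares and triangles mark library numbers 1, 2 and 3 and the bar the mean. Id3 lies at 13.1, 12.9 and 20.7 CPM in knockout-labelled libraries with BMP4 and at 1.88, 10.6 and 9.05 CPM in floxed-labelled ones.

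The response to BMP4 was not shown to differ between the genotype labels for any gene by the unblocked test (edgeR, 0 called, lowest edgeR adjusted p = 0.07, 839 genes at an unadjusted p under 0.05). DESeq2 called 15 genes and edgeR with the replicate block within genotype 7. Id2 rose more in knockout-labelled cells by log2 0.53 (SE 0.10, edgeR adjusted p = 0.121, DESeq2 adjusted p = 0.0263), and Id3 by log2 0.98 (edgeR adjusted p = 0.987). Cell cycle genes as a list lay higher in the knockout minus floxed difference (median log2 0.19, camera adjusted p = 0.000861, adjusted p = 0.99 with an estimated correlation). That call was lost without knockout-labelled untreated library 2 (0.569) or BMP4 library 3 (0.807), without floxed-labelled untreated library 1 (0.0927) or 3 (0.253) or BMP4 library 2 (0.0535), and in the 15 libraries (0.0688). Across all genes the BMP4 responses of the labels correlated at −0.03 (0.48 for genes with a mean of at least 10 CPM), and 54 of the 84 called in knockout-labelled cells (64.3%) had the same sign in floxed-labelled cells, or 45 of 46 (97.8%) of those with a mean of at least 10 CPM.

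TGF-β1 against BMP4 compares the ligands directly. In floxed-labelled cells Pmepa1 was 203 CPM with TGF-β1 and 0.614 CPM with BMP4 (log2 8.36, SE 0.12, edgeR adjusted p = 9.52e-20). The BMP targets Id2 (log2 1.60, SE 0.07, edgeR adjusted p = 7.85e-13), Id3 (log2 1.49, SE 0.38, edgeR adjusted p = 0.00451) and Smad6 (log2 3.99, SE 0.31, edgeR adjusted p = 4.11e-09) were also higher with TGF-β1 than with BMP4. Slc40a1 was lower with TGF-β1 (30.7 against 425 CPM, log2 −3.79). The counts were 5109 genes in floxed-labelled cells (2624 higher with TGF-β1, 2485 lower) and 4789 in knockout-labelled cells (2413 and 2376), where Pmepa1 stood at 194 and 0.394 CPM (log2 8.92, SE 0.13), Id2 at log2 1.72 and Smad6 at log2 3.80 (SE 0.28). Of 27 TGF-β targets 19 were higher with TGF-β1 and 2 lower in floxed-labelled cells (19 and 3 adjusted over the list alone, camera adjusted p = 2.62e-12), and 18 and 2 in knockout-labelled cells (camera adjusted p = 1.18e-11). Interferon-stimulated genes were lower with TGF-β1 in 21 of 30 cases and higher in 1 in floxed-labelled cells (camera adjusted p = 1.45e-05, adjusted p = 0.725 with an estimated correlation).

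Knockout-labelled against floxed-labelled untreated cells asks what loss of Smad1 changes without added ligand, with directions that rest on labels Lyz2 contradicts. Per the labels these groups also differ in Cre at Lyz2. No group was labelled as having Cre with intact Smad1. Effects of Cre, of its insertion and of Smad1 loss therefore cannot be told apart in any genotype comparison. Gsta3 (ENSMUSG00000025934), a glutathione transferase, was lower in knockout-labelled cells (55 ± 5.92 against 33.7 ± 1.53 CPM, log2 −0.71, SE 0.10, edgeR adjusted p = 0.00291). Lars2, the mitochondrial leucyl-tRNA synthetase, was higher (394 ± 12.5 against 1290 ± 36.3 CPM, log2 1.71, SE 0.38, edgeR adjusted p = 0.0287). The basement membrane collagen gene Col4a2 (8.01 ± 1.99 against 17.4 ± 3.26 CPM, log2 1.12, SE 0.19, edgeR adjusted p = 0.00696) and the growth factor gene Pdgfb (48.1 ± 3.57 against 64.1 ± 3.22 CPM, log2 0.42, SE 0.07, edgeR adjusted p = 0.00696) were higher. Ifitm6, an interferon-induced membrane protein (11.3 ± 0.85 against 5.52 ± 0.496 CPM, log2 −1.02, SE 0.19, edgeR adjusted p = 0.0111), the chemokine receptor Ccr1 (log2 −0.88, edgeR adjusted p = 0.0194) and the lipoprotein gene Apoe (5010 ± 264 against 3960 ± 133 CPM, log2 −0.34, edgeR adjusted p = 0.0158) were lower. In all 351 genes were called, 190 higher and 161 lower, with 76 higher and 4 lower at least 2-fold. That balance turned with total count scaling (184 higher and 225 lower), with limma on log2(FPKM + 0.1) (166 and 181), with no low-count filter (290 and 527) and without knockout-labelled library 2 (243 and 370) or floxed-labelled library 2 (95 and 115) or 3 (62 and 78). TEC transcripts made up 42 of the higher genes and 0 of the lower, and ribosomal protein genes were lower in 26 of 88 cases.

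Each library left out moved the untreated count. It was 27, 613 and 36 without knockout-labelled libraries 1, 2 and 3, and 73, 210 and 140 without floxed-labelled libraries 1, 2 and 3. Gsta3 was called in each of these fits (log2 −0.80 to −0.67). Lars2 was lost without any library but knockout-labelled library 2 (edgeR adjusted p 0.0645 to 0.105), Col4a2 without knockout-labelled library 3 (0.053), Pdgfb without library 1 (0.0614), Ifitm6 without library 1 (0.0608) or 3 (0.0692) and Apoe without library 1 (0.0851) or 3 (0.0709). Ccr1 was lost without knockout-labelled library 3 (0.0683) or floxed-labelled library 1 (0.0711) or 3 (0.0517). The 15 libraries gave 39 calls, of which 36 were among the 351, and a fit of the 6 untreated libraries alone gave 29. With the TEC share as a covariate edgeR called 0 genes.

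Monocyte markers were lower in untreated knockout-labelled cells as a list (median log2 −0.51, 0 of 11 called over all genes and 4 lower adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.397 with an estimated correlation). Ccr2, the receptor that monocytes use to leave marrow, was 593 ± 121 CPM in floxed-labelled and 402 ± 35.8 CPM in knockout-labelled cells (log2 −0.56, edgeR adjusted p = 0.0972). Dendritic cell markers (median log2 −0.40, 1 lower of 15, or 3 adjusted over the list alone), neutrophil markers (median −0.29), other chemokines and receptors (median −0.21, 1 lower, or 4 adjusted over the list alone), interferon-stimulated genes (median −0.19), immediate early and heat shock genes (median −0.16) and hypoxia genes (median −0.10, 1 lower) were lower as lists too (camera adjusted p = 0.0166 each, adjusted p = 0.397 to 0.759 with an estimated correlation). Smads and receptors were higher (1 of 25, the type II BMP receptor Bmpr2, or 2 adjusted over the list alone, camera adjusted p = 0.0255, adjusted p = 0.397 with an estimated correlation). All 8 lists lost the call without knockout-labelled library 2 (0.0761 to 0.137). Without knockout-labelled library 1 or 3 the losses were 3 (0.0732 to 0.125) and 2 (0.0529 and 0.0771), and without floxed-labelled libraries 1, 2 and 3 they were 2 (0.059 and 0.201), 3 (0.119 to 0.742) and 4 (0.0728 to 0.131). In the 15 libraries the Smad and receptor list (0.22) and the interferon list (0.0693) lost the call, and the pro-inflammatory list (lower, 0.0117) and cholesterol and lipid genes (higher, 0.00645) gained one. TGF-β targets had a median of log2 0.03, a mean of −0.01 and 0 calls (camera adjusted p = 0.604), and BMP targets a median of 0.09, a mean of −0.05 and 0 calls, or 1 lower adjusted over the list alone (camera adjusted p = 0.969).

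Knockout-labelled against floxed-labelled cells under TGF-β1 asks the same question with the ligand present, with directions that rest on labels Lyz2 contradicts. Gsta3 was again lower (65.7 ± 6.31 against 40.3 ± 2.82 CPM, log2 −0.70, SE 0.10, edgeR adjusted p = 0.0114) and Id2 was higher (66.9 ± 4.58 against 87.5 ± 3.61 CPM, log2 0.39, SE 0.06, edgeR adjusted p = 0.0186). The immunoglobulin heavy chain gene Ighm (41.6 ± 4.48 against 23.8 ± 2.39 CPM, log2 −0.80, SE 0.13, edgeR adjusted p = 0.0186), the inhibitory Fc receptor Fcgr2b (95.2 ± 8.02 against 63.4 ± 4.81 CPM, log2 −0.59, edgeR adjusted p = 0.0421) and the lipopolysaccharide co-receptor Cd14 (224 ± 15.5 against 168 ± 13.4 CPM, log2 −0.42, edgeR adjusted p = 0.0306) were lower. Col4a2 was higher (7.49 ± 1.71 against 14.2 ± 1.9 CPM, log2 0.93, edgeR adjusted p = 0.0421). In all 57 genes were called, 20 higher and 37 lower, and with RLE scaling 30 were, 14 higher and 16 lower.

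No gene kept its call under every library left out in this comparison: the count was 0, 9 and 8 without knockout-labelled TGF-β1 libraries 1, 2 and 3 and 0, 1 (Gsta3) and 16 without floxed-labelled ones. Gsta3 was lost without knockout-labelled library 1 (edgeR adjusted p = 0.0619) or floxed-labelled library 1 (0.0686), Ighm without knockout-labelled library 1 (0.0883) or 3 (0.0528) or floxed-labelled library 1 (0.0785) or 2 (0.0981), and Id2, Fcgr2b, Cd14 and Col4a2 without any 1 of the 6 (0.0516 to 0.107 for Id2, 0.0789 to 0.172 for Fcgr2b, 0.0707 to 0.143 for Cd14, 0.0815 to 0.193 for Col4a2). The replicate block gave 97 calls, DESeq2 189, and the 15 libraries 2 (Lyz2 and Dglucy, the latter named after its value was seen). Monocyte markers were lower (median log2 −0.47, 0 called and 5 lower adjusted over the list alone of 11, camera adjusted p = 0.000544, adjusted p = 0.415 with an estimated correlation), as were hypoxia genes (1 lower of 26, or 3 adjusted over the list alone, camera adjusted p = 0.000633, adjusted p = 0.415 with an estimated correlation). BMP targets were higher (median log2 0.17, 1 called of 14, or 3 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.415 with an estimated correlation). That call was lost without knockout-labelled TGF-β1 library 1, 2 or 3 (0.0623, 0.109 and 0.0875), without floxed-labelled library 1 or 3 (0.202 and 0.0742) and in the 15 libraries (0.0992). Dendritic cell markers (median log2 −0.28, camera adjusted p = 0.0244), neutrophil markers (median −0.26, camera adjusted p = 0.0471) and immediate early and heat shock genes (median −0.09, camera adjusted p = 0.049) were lower as well (adjusted p = 0.437 to 0.564 with an estimated correlation). Each of these 3 lost the call without any 1 of 3 libraries: dendritic markers without knockout-labelled library 2 (0.109) or floxed-labelled library 2 (0.0507) or 3 (0.108), neutrophil markers without knockout-labelled library 1 (0.257) or 2 (0.105) or floxed-labelled library 3 (0.295), and the early genes without knockout-labelled library 2 (0.184) or 3 (0.0682) or floxed-labelled library 2 (0.351). The 15 libraries added calls for other chemokines and receptors (0.0102), pro-inflammatory genes and fibroblast markers (0.00791 each), all lower.

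Knockout-labelled against floxed-labelled cells under BMP4 gave 4 genes, again in directions that rest on labels Lyz2 contradicts. Cpsf6 (ENSMUSG00000055531, chromosome 10, 117344673 to 117380015), a pre-mRNA 3′ end processing factor, was lower in knockout-labelled cells (125 ± 3.61 against 92.5 ± 5.94 CPM, log2 −0.44, SE 0.05, edgeR adjusted p = 0.00189). Its start lies 67 kb from that of Lyz2, where the labels place the Cre of knockout-labelled mice. Rnf17, a germ cell gene (2.52 ± 0.265 against 0.64 ± 0.138 CPM, log2 −1.97, SE 0.29, edgeR adjusted p = 0.0117), and Gsta3 (48.4 ± 3.24 against 32.2 ± 4.3 CPM, log2 −0.59, SE 0.10, edgeR adjusted p = 0.0358) were also lower, and Kif21b was higher (97.8 ± 2.87 against 118 ± 4.15 CPM, log2 0.27, SE 0.04, edgeR adjusted p = 0.028). Total count scaling called 2, Cpsf6 and Rnf17, 0 of them higher. Id2 (log2 0.26, edgeR adjusted p = 0.315), Id3 (log2 1.13, edgeR adjusted p = 0.446) and Smad6 (log2 0.93, edgeR adjusted p = 0.55) did not pass. Cpsf6 was called under each library left out, as the 1 gene without knockout-labelled BMP4 library 1 or 2, and as 1 of 2 without floxed-labelled library 2 (with Rnf17) or 3 (with Zkscan17, named after its value was seen). Rnf17 was lost without knockout-labelled library 1 (0.0696) or 2 (0.114) or floxed-labelled library 3 (0.0584), and Gsta3 (0.0526 to 0.133) and Kif21b (0.0518 to 0.2) without any 1 of the 6. The replicate block gave 10 calls and DESeq2 34, while a fit of only the groups compared called no gene, Cpsf6 included.

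Dendritic cell markers were lower under BMP4 in knockout-labelled cells as a list (median log2 −0.34, 0 called and 5 lower adjusted over the list alone of 15, camera adjusted p = 0.000398, adjusted p = 0.478 with an estimated correlation). Cell cycle genes were higher (median log2 0.19, camera adjusted p = 0.000104, adjusted p = 0.537 with an estimated correlation, 0.381 without knockout-labelled library 3). Interferon-stimulated genes were lower (median log2 −0.14, camera adjusted p = 0.000398, adjusted p = 0.539 with an estimated correlation, 0.698 without knockout-labelled library 2, 0.0525 without floxed-labelled library 1 and 0.0663 in the 15 libraries). Monocyte markers were lower (median log2 −0.37, camera adjusted p = 0.027, adjusted p = 0.537 with an estimated correlation), a call lost without knockout-labelled library 2 (0.479) or floxed-labelled library 2 (0.0578) or 3 (0.158). Neutrophil markers (median log2 −0.17, camera adjusted p = 0.0294, adjusted p = 0.537 with an estimated correlation) were lower too, a call lost without knockout-labelled library 1 (0.639) or 2 (0.192) or floxed-labelled library 3 (0.391). Other chemokines and receptors were lower (median log2 −0.21, camera adjusted p = 0.0435, adjusted p = 0.537 with an estimated correlation), a call lost without knockout-labelled library 2 (0.274) or floxed-labelled library 1 (0.0525) and in the 15 libraries (0.121). The 15 libraries added calls for matrix genes (0.0449) and cholesterol and lipid genes (0.000147), both higher.

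TEC transcripts and Malat1, a nuclear non-coding RNA, moved with the genotype label where its counts of calls were highest. TEC transcripts took 0.125% ± 0.012 of the counts in untreated knockout-labelled libraries and 0.097% ± 0.004 in floxed-labelled ones (n = 3 each), 0.113% ± 0.007 and 0.095% ± 0.004 with TGF-β1, and 0.099% ± 0.003 and 0.105% ± 0.002 with BMP4. Over 578 tested TEC transcripts the median knockout against floxed difference was log2 0.55 untreated, 0.32 with TGF-β1 and −0.09 with BMP4. Malat1 (ENSMUSG00000092341), outside the rule for the untreated comparison and named after its values were seen, was 1510 ± 138 CPM in untreated floxed-labelled and 2370 ± 280 CPM in knockout-labelled cells (log2 0.65, SE 0.10, edgeR adjusted p = 0.00399), log2 0.46 with TGF-β1 (edgeR adjusted p = 0.0421, called without knockout-labelled TGF-β1 library 3 and lost without any other, 0.0927 to 0.199) and log2 −0.04 with BMP4 (edgeR adjusted p = 0.949). Ribosomal protein genes took 2.993% ± 0.035 of counts in untreated floxed-labelled and 2.577% ± 0.11 in knockout-labelled libraries.

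**Figure D5:**
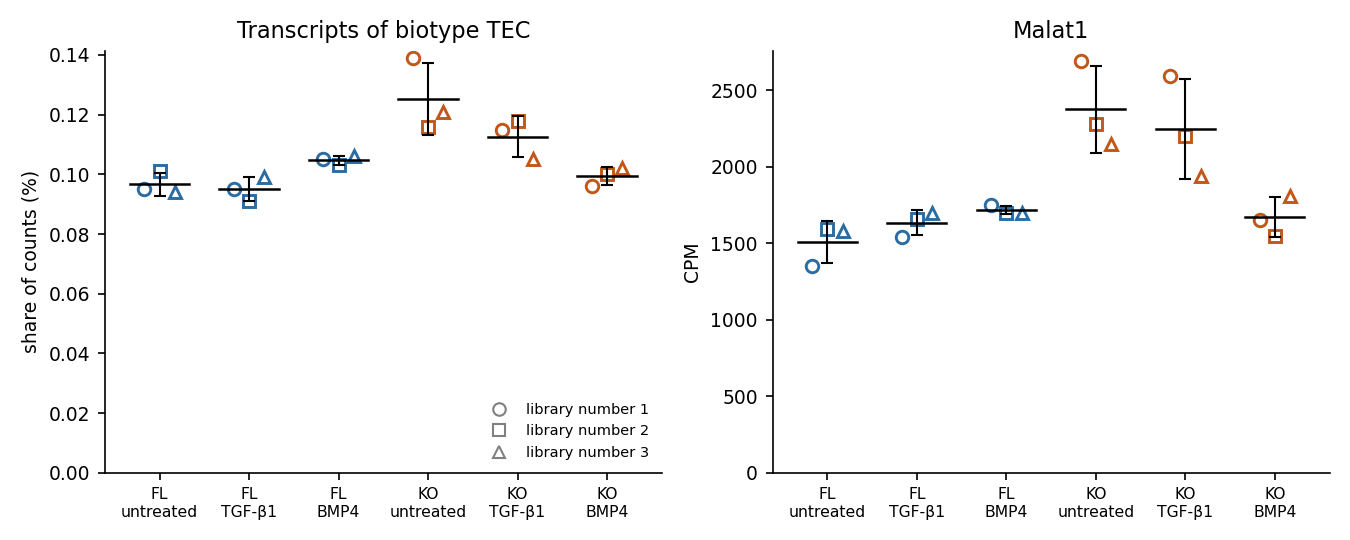
Share of counts in TEC transcripts (percent) and Malat1 (CPM) in each library by group, both on linear axes, with group mean and SD; circles, squares and triangles mark library numbers 1, 2 and 3. The untreated knockout-labelled group has the highest TEC mean, 0.125%, and with BMP4 the groups lie at 0.099% and 0.105%.

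Across the 3 treatments 30 genes were called between genotype labels in at least 2, 28 in 2 and 2 (Kif21b and Gsta3) in 3, with 0 in opposite directions. Of the 351 genes called untreated 344 (98%) had the same sign under TGF-β1 and 277 (78.9%) under BMP4. Of the 259 with a mean of at least 10 CPM they were 256 (98.8%) and 242 (93.4%). Same-numbered libraries of a label are paired across treatments, so part of this agreement may come from shared sources, and no value expected without a genotype difference was computed. Within 10 Mb of Lyz2, 5 of 81 tested genes were called untreated (1.94 expected, two-sided Fisher's exact p = 0.0445). They were Glipr1, Cpsf6, Yeats4, Lyz1 and Gm17849, named by position after their values were seen. Under TGF-β1 2 were called (Glipr1 and Mon2, Fisher's exact p = 0.0395) and under BMP4 1 (Cpsf6, Fisher's exact p = 0.0219), while the p was 0.0785, 1 and 0.0114 with a 5 Mb window and 0.282, 0.124 and 0.0421 with a 20 Mb one. Within 10 Mb of Smad1, 10 of 229 tested genes were called untreated (Fisher's exact p = 0.0741), 2 under TGF-β1 (Fisher's exact p = 0.223) and 0 under BMP4. Cpsf6 was log2 −0.37 untreated (edgeR adjusted p = 0.00399) and log2 −0.09 under TGF-β1 (edgeR adjusted p = 0.529). No chromosome differed in its share of calls after adjustment over the 21 chromosomes of a comparison.

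Within a genotype label the TGF-β1 and BMP4 responses share the untreated libraries, which alone correlates them. In floxed-labelled cells r was 0.17 (0.50 in 20 simulations with no effect) with a covariance of 0.033 (simulated 0.040), and in knockout-labelled cells r was 0.26 (0.52) with a covariance of 0.064 (simulated 0.043, highest 0.046). The simulations gave neither ligand an effect, so their r cannot be set against one that holds the large TGF-β1 response. They also left out the pairing of same-numbered libraries, which may change the covariance expected. In knockout-labelled cells 13 genes rose with both ligands (3.3 expected of independent lists), 29 fell with both (11.1 expected) and 6 moved in opposite directions. Part of that overlap may come from the shared untreated libraries.

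The authors' deposited table called 4133 genes for TGF-β1 in floxed-labelled cells, of which 4002 were among the 4841 called here, and 4003 in knockout-labelled cells, of which 3908 were among the 5084. For BMP4 it called 5 genes in floxed-labelled cells, 0 of them called here, and 54 in knockout-labelled cells, 47 of them among the 84. Between genotype labels it called 144 untreated (98 among the 351), 192 with TGF-β1 (50 among the 57) and 30 with BMP4 (3 among the 4).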

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

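The tests of exchanged labels, of 1 mislabelled animal, of the Lyz1 copy, of the TEC covariate, of the spread with the block and of an equal genotype effect in all treatments were chosen after the result was seen, and the other tests in this part before. The response of Id2 to TGF-β1 differed between the genotype labels in a test of that difference, with a rise larger by log2 0.65 (SE 0.10) in knockout-labelled cells (edgeR adjusted p = 0.0433). The call was lost without any 1 of 10 of the 12 libraries (edgeR adjusted p 0.0518 to 0.301), with the block over all groups (0.105), with the TEC covariate (0.101) and in the 15 libraries (1). With the replicate block within genotype the same test called 1 gene for TGF-β1, Id2 (log2 0.66, edgeR adjusted p = 0.0128). For BMP4 the blocked test called 7 genes, all lower in the knockout minus floxed difference. They were Malat1 (log2 −0.69, edgeR adjusted p = 0.000987), A930037H05Rik (log2 −1.49) and 5 TEC transcripts, Gm37084, Gm37352, Gm37033, Gm37472 and Gm47603 (log2 −1.32 to −3.04), named after their values were seen.

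Lyz2 was lower in the floxed-labelled libraries, although the Cre insertion in LyzM-Cre mice interrupts Lyz2 and the labels put it in the knockout group. A candidate explanation is that the genotype labels are exchanged. The rise of Id2 with BMP4 was larger in knockout-labelled cells by log2 0.53 (SE 0.10), the direction an exchange would give. It was not called (edgeR adjusted p = 0.121). Knockout against floxed, Id2 was log2 −0.27 untreated (edgeR adjusted p = 0.0648) and 0.26 with BMP4 (edgeR adjusted p = 0.315), so the untreated level contributes. Other causes of a larger response were not tested. Smad1 was lower in knockout-labelled cells by more than 2 SE in 3 of 3 treatments, but its whole-gene count does not decide, since it may hold reads outside the deleted part. A wrong label for only the floxed-labelled libraries numbered 1 does not account for the whole pattern, since without them Lyz2 still differed by log2 0.71 (SE 0.06) untreated. That test leaves those libraries out, so it does not show whether they are mislabelled too. Reads assigned to Lyz1 are excluded, since Lyz1 reached at most 9.34 CPM in the libraries numbered 1, against the 9760 and 9680 CPM of Lyz2 in untreated floxed-labelled libraries 2 and 3 that it would have to replace. Lyz2 was 61.3% of the knockout-labelled median in the floxed-labelled libraries numbered 2 and 3 and 0.395% in those numbered 1, so Cre at Lyz2 in the floxed-labelled mice, with labels exchanged or not, stays open and was not tested. No biological explanation was tested, because the design gives none for less Lyz2 without Cre.

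TEC transcripts were higher in untreated knockout-labelled libraries (0.125% against 0.097% of counts). Carry-over of nuclear or unspliced RNA that varies between libraries may contribute: of 273 called protein-coding genes, 77.3% had a slope on the TEC share within groups of the same sign as their genotype difference, against a median of 59.7% in 10000 permutations of the share within groups (one-sided permutation p = 0.0434). The genes were called on libraries that also enter the slopes. The permutations treat same-numbered libraries as unpaired. For both reasons this p-value may be too small. With the TEC share as a covariate the 351 genes went from a median size of log2 0.30 to 0.22 and from a median SE of 0.06 to 0.12, 346 kept their sign and 0 were called, so the calls ended through both a smaller difference and a larger error. The genotype difference in TEC share was not equal in all treatments, at −0.00546 percentage points with BMP4 against 0.0283 untreated (SE of the change 0.0071). With TGF-β1 it was 0.0175 points. The SE covers only the spread between libraries of a group. An equal genotype effect masked by carry-over that differs between whole groups is therefore not excluded. An effect of genotype on nuclear RNA that is absent with BMP4 was not tested and stays open beside carry-over.

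BMP4 gave 84 calls in knockout-labelled and 0 in floxed-labelled cells, although the direct test of the difference called 0 genes. With the replicate block within genotype the counts were 472, 53 and 7. Over all genes the spread between floxed-labelled libraries was not larger. Their median SE was 0.956 of that in knockout-labelled ones and 0.982 of it with the block. A median over all genes cannot exclude a larger spread in the few that respond to BMP4. Id3, for example, was 7.19 ± 4.67 CPM in floxed-labelled and 15.5 ± 4.44 CPM in knockout-labelled libraries with BMP4. These SDs are similar, and only relative to the mean is the floxed-labelled spread larger. It rests on library 1, the lowest of its group in Id3 and near 0 in Lyz2. The state of the untreated knockout-labelled libraries may account for part of the difference: the 65 genes lowered by BMP4 lay a median of log2 0.86 above floxed-labelled cells before treatment and −0.12 with BMP4, while in floxed-labelled cells BMP4 moved them by −0.03. These genes were chosen on the same untreated libraries, which by itself raises the median of 0.86, so it does not measure how large that part is. The 19 raised genes were chosen in the same way, so their medians (log2 −0.14 untreated and 0.01 with BMP4) add no support.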

How the results depend on the processing

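The fit of 15 libraries, the TEC covariate, the block within genotype with 15 libraries, and the list tests in 15 libraries or with the block within genotype were chosen after seeing the data; the other alternatives were chosen before. Over all alternatives, 9374 of the values for called genes named by the rule kept direction and call, 681 lost the call and 1 changed sign, and of values for genes not called 7314 stayed and 99 passed. Smad1 gave no call in any of its 51 alternatives, with log2 −0.25 to −0.22 untreated, −0.29 to −0.15 with TGF-β1 and −0.28 to −0.19 with BMP4 when libraries were left out. List calls held in 393 values and were lost in 141, and 91 values for other lists passed. Most of these values came from leaving out 1 library, where 249 held and 63 were lost. With an estimated correlation in camera 5 held and 46 were lost. With fry, another list test in limma, 29 held and 22 were lost, and 32 other lists passed. With 3 libraries per group the genotype counts rest on single libraries, and genes near the floor of 3 counts, such as Id1, give imprecise folds.

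The TGF-β1 counts stayed within 1.5 times under all alternatives, including 4202 to 4510 with a library left out in floxed-labelled and 4352 to 4660 in knockout-labelled cells, and 4370 to 4508 and 4128 to 4406 against BMP4. Counts that moved further follow, and where not stated the cause was not tested. With no low-count filter, which tests more genes, the knockout against floxed counts went from 351 to 817 untreated (35.5% higher), from 57 to 394 with TGF-β1 and from 4 to 287 with BMP4, those of BMP4 from 0 to 69 in floxed-labelled and 84 to 240 in knockout-labelled cells, and the interactions from 1 to 8 (TGF-β1) and 0 to 48 (BMP4). DESeq2 gave 539, 189, 34, 14 and 181 in the same order and 15 for the BMP4 interaction. Fits of only the groups compared, which estimate the spread from fewer libraries, gave 29 untreated, 19 with TGF-β1, 0 with BMP4, 2 for BMP4 in knockout-labelled cells (Tns1 and Id3) and 0 for the TGF-β1 interaction. For the genotype comparisons these fits also leave out the paired libraries of other treatments. Which of these lowered the counts was not tested.

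RLE scaling gave 30 for the genotypes under TGF-β1, and total count scaling gave 2 under BMP4 and 0 for the TGF-β1 interaction. The replicate block over all groups gave 97 with TGF-β1, 10 with BMP4 and 0 for the TGF-β1 interaction. The replicate block within genotype gave 53 for BMP4 in floxed-labelled cells, 472 in knockout-labelled cells and 7 for the BMP4 interaction. Among named genes that block added 16 calls and ended 0, and it changed no other list call than those printed beside the results. limma on log2(FPKM + 0.1) gave 18 for the genotypes with TGF-β1, 0 for the TGF-β1 and 2 for the BMP4 interaction, and on log2(FPKM + 1) 0 and 3.

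The 15 libraries gave 39 untreated, 2 with TGF-β1, 1 for BMP4 in floxed-labelled cells (Id3) and 0 for the TGF-β1 interaction, and with the block within genotype 18 for BMP4. The TEC covariate gave 0 untreated, 0 with TGF-β1, 0 for BMP4 in knockout-labelled cells and 0 for the TGF-β1 interaction. Leaving out 1 library gave 27 to 613 untreated, 0 to 16 with TGF-β1, 1 to 5 with BMP4, 0 to 1 for BMP4 in floxed-labelled cells, 4 to 112 in knockout-labelled cells, 0 to 1 for the TGF-β1 interaction and 0 for the BMP4 interaction. Results that changed sign were Fam196b untreated with the TEC covariate (log2 −0.08, SE 0.46, against 1.41), the interferon list for BMP4 in knockout-labelled cells without BMP4 library 1 (camera adjusted p = 0.0172 against 0.889), and genes near Lyz2 with TGF-β1 in a 5 Mb window (Fisher's exact p = 1 against 0.0395), which holds fewer genes.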

Other observations

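The splits of the samples reported in this part were tested after the result was seen. Several genes not described in the report changed with TGF-β1. Tmeff1, a transmembrane protein with follistatin-like domains, rose by log2 7.20 (SE 0.26) in floxed-labelled and 7.52 (SE 0.27) in knockout-labelled cells. Cd300lf, an inhibitory receptor of myeloid cells that binds lipids, rose from 4.63 to 54.6 CPM (log2 3.56, SE 0.11) in floxed-labelled cells. In knockout-labelled cells the VEGF receptor gene Flt1 rose by log2 3.13 (SE 0.28) and the glycosyltransferase gene B3gnt5 fell by 3.62 on the log2 scale.

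In each comparison of 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled split gave the highest count, 1 of the 10 splits, in knockout against floxed cells untreated (351 genes, highest other 0), with TGF-β1 (57, highest other 0) and with BMP4 (4, highest other 0), and for TGF-β1 (4841 and 5084, highest other 0), BMP4 in knockout-labelled cells (84, highest other 0) and TGF-β1 against BMP4 (5109 and 4789, highest other 0). For BMP4 in floxed-labelled cells 10 of 10 splits gave 0 genes. In each comparison of ligands the 3 other splits that part as many same-numbered pairs also called 0. Splits that mix groups put any real difference into the spread within them, which lowers their counts. Their 0 calls therefore do not measure chance. For the TGF-β1 interaction 14 of 100 splits called at least 1 gene, the labelled one included. These splits exchange treatments, which carries the TGF-β1 response itself into the interaction or the spread, so their share does not measure chance. The highest other split, which is among the 14 others that part as many same-numbered pairs, called 6754 genes through that structure of the samples. For the BMP4 interaction the labelled split called 0 genes, which all 100 of 100 splits reach, so that count tests nothing. The highest other called 18, and 3 among the 15 others that part as many pairs.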
